A study of Rattus norvegicus with 15 samples.

How the data were processed

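RNA from synovial tissue of rats, in 15 libraries, was sequenced, 5 untreated control rats, 5 rats with adjuvant-induced arthritis (AIA) and 5 AIA rats given an antibody that the labels call anti-cANGPTL4. Per the labels' protocols, arthritis was started with 100 uL of complete Freund's adjuvant injected into the skin of the tail, and the antibody was given into the peritoneum on repeated days each week. The labels name no vehicle or isotype antibody for the AIA group and no batch. RNA was taken up with a column kit and 1.3 ug of total RNA went into each mRNA library, made with a SMARTER kit, per the labels' protocols. Samples were grouped by their titles, and each replicate keeps the number in its title. No replicate number occurs in more than 1 group, so nothing pairs the rats.

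The authors deposited a table of raw counts per gene symbol and a table of FPKM values, with 1 column per library in each. Both hold 23342 symbols. The counts are whole numbers and carry no normalization. The deposited FPKM equals the count divided by a fixed gene length and by the total count of the library, which held within 0.1% for 100% of the 291027 values with a count. It therefore adds no information to the counts except the gene length, and the counts were used for the main tests. The aligner and the counting program are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, while 20949 of the symbols match a symbol of the rat RefSeq table of assembly GRCr8 and a further 117 match a synonym. The annotation behind the counts is therefore uncertain, genes are given by symbol only, and no coordinates are printed. Reads of near-identical genes can be split between copies by the counting, so RT1 genes of the major histocompatibility complex, globins, Orm1, Kng2, Ccl12 and Slfn13 are uncertain. Library strandedness is not stated, so reads of a gene and of an antisense partner cannot be told apart.

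Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group factor, which left 16046 genes for testing and removed 7296. TMM factors were computed, 1 dispersion model was fitted over all 15 libraries with group as the only term, and each pair of groups was compared with the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over the 16046 genes, and a gene was called at an adjusted p under 0.05. Each library is taken as 1 rat, so p-values measure spread between rats. The title of antibody replicate 21_8 carries 2 numbers, and the labels do not say whether it is 1 rat or a pool, so n = 5 in that group rests on this assumption. Log2 CPM values use a prior count of 2. Fold changes are given as log2 with the standard error (SE) implied by the F statistic. The Angptl4 level was also compared with two-sided exact permutation tests of 5 against 5 libraries, which cannot give a p below 0.0079.

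Before the data were examined, 23 pathway lists and 22 cell type lists were fixed, with 838 different gene names, of which 790 were in the table and 720 were tested. A list needed 5 tested genes, which 44 of the 45 lists had. The sex-linked list, with 1 tested gene, was not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 44 lists, and again with an estimated correlation and with fry. A list score is the mean log2 CPM of the tested members of a list, relative to the control mean. Lists share genes (Col1a1 is in the lists of matrix, bone, osteoblast and tendon genes), so they are not independent. Counts of called members are given over all genes tested and, where marked, adjusted over the list alone.

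The genes named in the text follow a rule set at the same time. They are Angptl4, the 8 genes with the largest change in each direction among called genes with an average log2 CPM of at least 1, a full symbol and no overlap between the groups, up to 4 called members of each list with the largest change, or its 2 members of highest expression where none was called, and the 8 genes of lowest p among those that moved back under the antibody. Not every gene the rule allows is printed. Ccl20 has no count in any control library and is left out.

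Opposite changes in AIA against control and antibody against AIA are favoured by the AIA libraries they share. Unchanged groups were therefore simulated 100 times for signs and covariance, and the 5 AIA libraries were split into 2 and 3 in all 10 ways. The test was also checked on simulated data with known changes, drawn from the means, library sizes and fitted dispersions of these libraries. Genes were drawn independently, with no subgroups of libraries within a group. The shares below hold for that setting, and the share of unchanged genes among calls may be higher in the real libraries. For AIA against control on 15910 simulated genes, 26.9% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 87.7% of those changed 4-fold were called, and 2.29% of the calls were unchanged genes. For antibody against AIA on 15903 genes the shares were 40.9%, 74.6% and 93.8%, with 2.84% unchanged genes among the calls. For antibody against control on 15906 genes they were 31.8%, 68.7% and 87.5%, with 3.15%.

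The alternatives were DESeq2 1.42.0 (size factors, and its Wald test), no filter on low counts, a filter of 10 counts in 10 libraries, a fit of only the 10 libraries compared, limma voom with sample weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold limit, the skeletal muscle and adipocyte scores as covariates, and leaving out each library. Added after the data were seen were Xist as a covariate and removal of the 2 libraries with skeletal muscle transcripts. The adipocyte covariate for the lists and for the genes moved back, and DESeq2 for Angptl4, were also added then. Changing TMM to DESeq2 size factors moved the median log2 fold change by 0.01 or less in each comparison. Total counts ran from 31172215 to 34084345 per library, so 3 counts, the floor used for a gene with none, equal 0.088 to 0.0962 CPM, which covers counting error only. No replicate pair was identical, since the chi-square per degree of freedom between counts of 2 replicates was at least 22.79.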

Results

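Synovial tissue, the lining of the joint, was sequenced in 15 libraries, 3 groups of 5. Each library is taken as 1 rat, although the title of antibody replicate 21_8 carries 2 numbers and does not say whether it is 1 rat. Control rats were untreated. Rats of the AIA group had adjuvant-induced arthritis, an immune arthritis that follows injection of an oil with killed mycobacteria, and a further group of AIA rats received the anti-cANGPTL4 antibody of the labels. ANGPTL4 is a secreted protein best known as an inhibitor of lipoprotein lipase. The series title places the antibody in the context of bone protection in arthritis. The comparisons ask what AIA changed in the synovium, what differed between treated and untreated AIA rats, and what still differed from control under the antibody. Totals ran from 31172215 to 34084345 counts per library. Spearman correlations between replicates across genes were 0.978 to 0.99 in control, 0.963 to 0.99 in AIA and 0.983 to 0.993 in the antibody group. The first principal component held 26.3% of the variance. It set AIA replicates 18, 19 and 23 (-61.8, -72.6 and -44.6) apart from all other libraries. AIA replicates 5 and 13 (9 and 6.37) lay within the range of the control and antibody libraries, -2.89 to 29.5.

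Angptl4, which encodes the protein the antibody binds, was measured at 7.64 ± 0.36 log2 CPM in control, 8.14 ± 0.78 in AIA and 8.64 ± 0.39 in the antibody group (mean ± SD, n = 5 each). AIA against control was not called (log2 fold change 0.64 ± 0.31 SE, edgeR adjusted p = 0.25, exact permutation p = 0.246), and neither was antibody against AIA (0.36 ± 0.31, edgeR adjusted p = 0.532, exact permutation p = 0.222). Without AIA replicate 13 these became 0.318 and 0.684, and antibody against AIA became 0.188 without AIA replicate 23 and 0.23 without antibody replicate 3, with no call in any. The antibody group stood 2.01-fold above control with no overlap of the libraries. The exact permutation p of 0.0079 is the smallest that 5 against 5 can give, the edgeR adjusted p was 0.0601, and DESeq2 gave an adjusted p of 0.0117. These are transcript levels; the protein was not measured in the data used here. Of the 25 tested genes of the ANGPTL4 and lipid handling list, 1 was called lower in AIA against control (Angptl2, log2 fold change -0.43), 0 in antibody against AIA and 2 lower in antibody against control (Fn1, -0.93, and Itgb5, -0.56). Adjusted over the list alone, 0, 0 and 5 were called, the last with 1 higher and 4 lower.

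**Figure D1:**
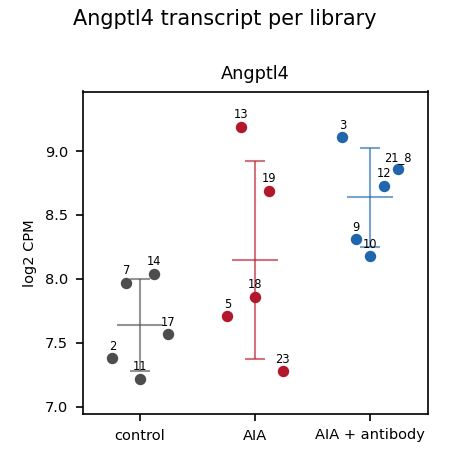
Angptl4 transcript level per library (log2 CPM, vertical axis) in the 3 groups. Points are libraries with their replicate numbers, and bars show the mean ± SD of 5; the antibody libraries lie between 8.18 and 9.11 and the control libraries between 7.22 and 8.04.

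Transcripts of T cells, neutrophils, antigen presentation, complement and acute inflammation were higher on average in the AIA libraries than in control. Of 19 tested T and NK cell genes, 15 were higher and 0 lower (15 and 0 adjusted over the list alone), with a median log2 fold change of 2.04. Cd3e, a chain of the T cell receptor complex, rose by 3.15 ± 0.65 (SE) and Cd8a, the co-receptor of cytotoxic T cells, by 2.92 ± 0.39 on the log2 scale. The T and NK score was 1.36 to 2.19 in the 5 AIA libraries and -0.52 to 0.37 in control. This list was called by camera (adjusted p = 5.32e-15), and its adjusted p = 0.00993 with an estimated correlation. Of 15 neutrophil genes, 7 were higher (9 adjusted over the list alone), among them S100a8 and S100a9, the subunits of calprotectin (11.9-fold and 12.1-fold), and the neutrophil collagenase Mmp8 (14.4-fold, edgeR adjusted p = 0.0141). The neutrophil score was 1.11 to 3.81 in AIA and overlapped with control, where replicate 7 was at 1.53. Erythroid and marrow scores (0.52 to 1.92 in AIA) rose with it, and blood or marrow in the piece was not tested as a source. The camera adjusted p of the neutrophil list was 1.07e-08, and the adjusted p = 0.217 with an estimated correlation. Of 14 genes of MHC class II antigen presentation, 8 were higher (10 adjusted over the list alone), including the class II transactivator Ciita (log2 fold change 1.37) and the co-stimulator Cd80 (1.60). By camera the adjusted p was 1.68e-08, and the adjusted p = 0.221 with an estimated correlation. Of 12 dendritic cell genes, 6 were higher (6 adjusted over the list alone), including Itgax at 1.40 and Ccr7 at 1.46. For this list the camera adjusted p was 2.61e-05, and the adjusted p = 0.153 with an estimated correlation.

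The lists of complement, chemokines, NF-kappaB targets, and JAK-STAT3 and acute phase genes were called higher, and that of proinflammatory cytokines was not. C3, the central complement component, was 15-fold higher in AIA (log2 fold change 3.91 ± 0.35, edgeR adjusted p = 3.66e-05), and complement factor B (Cfb) and properdin (Cfp) rose by 1.85 and 1.14 on the log2 scale. Cd55, a complement inhibitor on cell surfaces, was lower at -1.23. Of the 20 complement genes, 8 were higher and 1 lower (9 and 3 adjusted over the list alone). Camera gave adjusted p = 0.0121, and adjusted p = 0.587 with an estimated correlation. Among 23 chemokines, 12 were higher and 3 lower (14 and 3 adjusted over the list alone), including Cxcl11 (3.29) and Ccl19 (2.40). As a list, the camera adjusted p was 6.07e-05, and the adjusted p = 0.172 with an estimated correlation. Of 22 NF-kappaB targets, 9 were higher (13 higher and 1 lower adjusted over the list alone), led by Il1rn, the interleukin-1 receptor antagonist, at 2.57 ± 0.28. Tested together, the camera adjusted p was 5.09e-06, and the adjusted p = 0.153 with an estimated correlation. Of 19 genes of the JAK-STAT3 and acute phase list, 9 were higher (12 adjusted over the list alone), including Lcn2 (2.06 ± 0.25) and the feedback inhibitor Socs3 (1.61 ± 0.35). The camera adjusted p was 2.01e-05, and the adjusted p = 0.178 with an estimated correlation. The proinflammatory cytokine list had camera adjusted p = 0.215, although Il1b (2.11 ± 0.39) and Csf3 (2.72 ± 0.66), encoding interleukin-1 beta and granulocyte colony-stimulating factor, were higher. Of its 16 genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone).

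Matrix and proliferation genes were also higher in AIA on average, and again not alike in the 5 libraries. Of 30 genes of fibrillar collagens and matrix, 14 were higher (21 higher and 2 lower adjusted over the list alone), among them Col12a1 (log2 fold change 3.13 ± 0.68), the proteoglycan lumican (Lum, 2.43 ± 0.56) and the collagen cross-linking enzyme Lox (2.35 ± 0.46). The matrix score was 1.73, 1.13 and 1.15 in AIA replicates 18, 19 and 23, and -0.08 and -0.01 in AIA replicates 5 and 13. Of 30 cell cycle genes, 19 were higher (26 adjusted over the list alone), including Top2a (3.16 ± 0.55) and Cenpf (3.18 ± 0.62). The cell cycle score was 2.07, 1.59 and 2.09 in replicates 18, 19 and 23 against 0.33 and 0.50 in replicates 5 and 13. By camera the adjusted p was 6.92e-07 for matrix and 5.7e-14 for cell cycle, and the adjusted p = 0.449 and 0.221 with an estimated correlation. Markers of tendon and ligament followed the same libraries, with scores of 2.01, 1.09 and 1.51 against -0.63 and -0.80, and the list of 8 was not called (2 higher, 1 lower, camera adjusted p = 0.284). Skeletal muscle transcripts stood apart in AIA replicate 19 (score 7.12) and control replicate 2 (6.02), with every other library at -0.63 or below. Of 20 matrix metalloproteinases and aggrecanases, 9 were higher (10 higher and 1 lower adjusted over the list alone), including stromelysin Mmp3 (1.37) and aggrecanase Adamts4 (1.68). For this list the camera adjusted p was 5.09e-06, and the adjusted p = 0.153 with an estimated correlation.

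**Figure D2:**
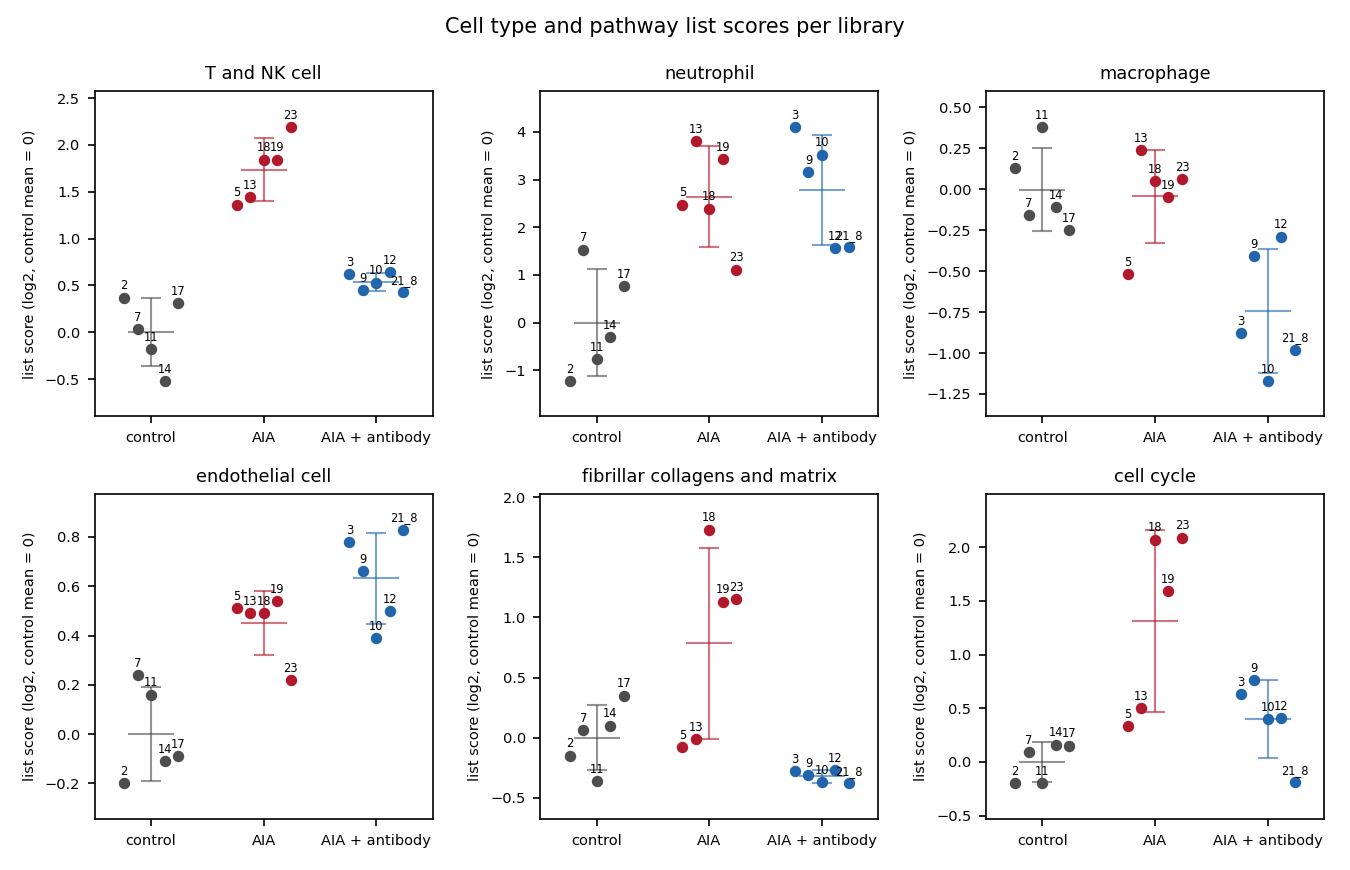
Scores of 6 fixed lists per library (mean log2 CPM of the members, control mean set to 0, vertical axis) in the 3 groups. Points are libraries with their replicate numbers and bars the mean ± SD of 5; T and NK scores of AIA lie at 1.36 to 2.19 and those of the antibody group at 0.43 to 0.64, while AIA replicates 18, 19 and 23 carry the high matrix and cell cycle scores.

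Markers of resident cells of the joint, and of erythroid cells, changed in both directions. Markers of lining synovial fibroblasts fell, with 0 higher and 6 lower of 12 (1 and 7 adjusted over the list alone), among them Clic5 (log2 fold change -1.52 ± 0.22) and Hbegf (-1.29 ± 0.22). Camera gave adjusted p = 8.09e-06, and adjusted p = 0.153 with an estimated correlation. Schwann cell and nerve markers were lower in 4 of 12 (5 adjusted over the list alone). As a list, the camera adjusted p was 4.79e-05, and the adjusted p = 0.172 with an estimated correlation; 0 members were called once both libraries with muscle transcripts were removed. Of 18 endothelial genes, 7 were higher (8 higher and 2 lower adjusted over the list alone), led by the leukocyte adhesion molecules E-selectin (Sele, 1.99 ± 0.28) and P-selectin (Selp, 1.93 ± 0.24). Tested together, the camera adjusted p was 2.64e-05, and the adjusted p = 0.316 with an estimated correlation. Erythroid genes were higher in 7 and lower in 1 of 18 (10 and 1 adjusted over the list alone), including Alas2 (2.22 ± 0.36), the enzyme that starts haem synthesis in red cells. The camera adjusted p was 2.93e-05, and the adjusted p = 0.285 with an estimated correlation. The lists of macrophage (1 higher, 1 lower of 19), osteoclast (1 of 6 higher), osteoclast differentiation (2 higher, 1 lower of 20), osteoblast and bone formation (2 higher, 1 lower of 17), adipocyte (1 higher, 1 lower of 18), hypoxia and glycolysis (1 of 24 higher) and PPAR targets of fatty acid oxidation (0 of 18) were not called. Even so, osteoclast scores were 0.365 to 0.981 in AIA and -0.184 to 0.0869 in control, without overlap. Osteoclast differentiation scores were 0.16 to 0.617 in AIA and -0.19 to 0.151 in control, also without overlap. Scores of the other lists in this group overlapped between AIA and control. Single bone-related genes passed, with Oscar, an osteoclast co-stimulatory receptor, at 3.51 ± 0.54, and Phex, an endopeptidase of bone-forming cells, at -1.40 ± 0.32.

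In all, 817 genes were higher and 553 lower in AIA against control, 498 and 158 of them by at least 2-fold. Large increases without overlap included those of Tnn, encoding tenascin N (4.82 ± 4.85 log2 CPM in AIA and -2.07 ± 0.74 in control, mean ± SD), Ubd, a ubiquitin-like modifier induced by cytokines (37-fold, edgeR adjusted p = 1.25e-05), Kng2, encoding a kininogen (22.4-fold), and Megf6 (15.8-fold). Large decreases without overlap included the extracellular matrix gene Tnr (10.2-fold lower), Car10 (4.80-fold lower), the BMP antagonist Grem1 (4.66-fold lower), Pappa2 (4.45-fold lower) and Cd5l, a protein secreted by macrophages (3.83-fold lower). Of the 1370 called genes, 818 had no overlap between the groups, and 6.42% of all tested genes had none, against 0.794% by chance. Without AIA replicate 18 or control replicate 14 the higher count was 522 or 541, and without the 2 libraries with muscle transcripts the counts were 334 higher and 238 lower. With 1 library left out, the calls of Angptl2 and Ccr7 were lost in 8 of 10 runs. Those of Ccl19 and Mmp3 were lost in 5 and those of S100a9 and Adamts4 in 1. With an estimated correlation 1 of the 15 lists called by camera (13 higher, 2 lower) passed.

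Matrix, T cell, MHC class II and macrophage transcripts were lower in the antibody group than in the AIA group. Of 30 matrix genes, 0 were higher and 18 lower (0 and 24 adjusted over the list alone), with a median log2 fold change of -1.19. Lum was at -3.10 ± 0.58, versican (Vcan) at -2.46 ± 0.52 and Lox at -2.30 ± 0.46 (SE). All 5 antibody libraries had matrix scores of -0.38 to -0.27, below every AIA library, and the AIA spread is the one described above, with replicates 18, 19 and 23 high. By camera the adjusted p was 3.86e-13, and the adjusted p = 0.294 with an estimated correlation. T and NK genes were lower in 7 of 19 (14 adjusted over the list alone), among them Cd3e (-2.26 ± 0.61), Il7r (-2.00 ± 0.40) and Cd2 (-1.91 ± 0.35). For this list the camera adjusted p was 1.13e-09, and the adjusted p = 0.0633 with an estimated correlation. Their scores were 0.43 to 0.64 in the antibody group and did not overlap with the 1.36 to 2.19 of AIA. Of 19 macrophage genes, 5 were lower (14 adjusted over the list alone), including Adgre1, the F4/80 antigen (-1.07 ± 0.19), Mrc1, the mannose receptor (-0.81 ± 0.19), and Gpnmb (-1.14 ± 0.24). Camera gave adjusted p = 2.47e-08, and adjusted p = 0.294 with an estimated correlation. MHC class II genes were lower in 5 of 14 (13 adjusted over the list alone), with Cd80 at -1.46 ± 0.32, camera adjusted p = 2.47e-08 and adjusted p = 0.294 with an estimated correlation. Dendritic cell genes were lower in 4 of 12 (7 adjusted over the list alone), including Clec10a (-1.30). As a list, the camera adjusted p was 0.00123, and the adjusted p = 0.294 with an estimated correlation. Of 20 complement genes, 3 were lower (7 adjusted over the list alone), including C1s (2-fold lower) and C1qa (-0.72). Tested together, the camera adjusted p was 2.37e-06, and the adjusted p = 0.294 with an estimated correlation.

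Metalloproteinases were lower under the antibody than in AIA, as were 3 genes of the osteoclast differentiation list, an inhibitor of osteoclast formation among them. Of 20 matrix metalloproteinases and aggrecanases, 7 were lower and 1 higher (9 and 1 adjusted over the list alone), including the gelatinase Mmp2 (log2 fold change -1.73 ± 0.24), Mmp16 (-1.81 ± 0.39) and Mmp11 (-1.49 ± 0.30). The camera adjusted p was 0.000433, and the adjusted p = 0.294 with an estimated correlation. In the list of osteoclast differentiation and function, 3 of 20 were lower (5 adjusted over the list alone), namely Ctsk, the main collagen-degrading protease of osteoclasts (-1.33 ± 0.23), Tyrobp (-0.75 ± 0.21) and Tnfrsf11b, encoding osteoprotegerin, a decoy receptor that inhibits osteoclast formation (-0.87 ± 0.21). Its camera adjusted p was 0.0103, which rose to 0.0523 without AIA replicate 13, and the adjusted p = 0.294 with an estimated correlation. The separate list of osteoclast markers was not called (1 of 6 lower, camera adjusted p = 0.0516), and of the 3 osteoclast differentiation genes called in AIA, 0 moved back and 2 stayed called against control. Cell cycle genes were lower in 8 and higher in 1 of 30 (23 and 1 adjusted over the list alone), including Top2a (-2.07 ± 0.53). For this list the camera adjusted p was 5.16e-08, and the adjusted p = 0.364 with an estimated correlation; without AIA replicate 18 or antibody replicate 21_8, 0 were called lower. Tendon and ligament markers were lower in 4 of 8 (6 adjusted over the list alone), including Thbs4 (-2.82 ± 0.55), and chondrocyte markers in 4 of 15 (5 adjusted over the list alone), including Comp (-2.28 ± 0.51), with camera adjusted p = 0.00373 and 0.045 and adjusted p = 0.364 and 0.518 with an estimated correlation. Without antibody replicate 10 the chondrocyte list was at adjusted p = 0.163. Skeletal muscle markers had 0 of 16 called (15 lower adjusted over the list alone), with adjusted p = 0.708 with an estimated correlation, and their camera adjusted p of 0.0226 became 0.68 without AIA replicate 19. The lists of protease inhibitors (2 of 13 lower), sublining fibroblast (4 of 14 lower), proinflammatory cytokines (0 of 16) and B and plasma cell (0 of 14) were called lower by camera, with adjusted p = 0.0182, 0.0226, 0.021 and 0.00965, and adjusted p = 0.294, 0.443, 0.294 and 0.294 with an estimated correlation. Each of these 4 lost its call when 1 library was left out, with adjusted p = 0.0523 (without AIA replicate 13), 0.0673 (without AIA replicate 19), 0.0683 (without antibody replicate 21_8) and 0.0685 (without antibody replicate 12).

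Higher transcripts under the antibody were fewer and smaller in change. Interferon response genes were higher in 2 of 26, Gbp5 (log2 fold change 0.57 ± 0.13) and Tap1 (0.33 ± 0.09), and 6 were called adjusted over the list alone; 25 of the 26 had a positive fold change. Camera gave adjusted p = 5.02e-07, and adjusted p = 0.294 with an estimated correlation. Adipocyte genes were higher in 2 of 18 (4 adjusted over the list alone), the hormone leptin (Lep, 1.68 ± 0.37) and the insulin-regulated glucose transporter Slc2a4 (0.92 ± 0.23). As a list, the camera adjusted p was 2.66e-06, and the adjusted p = 0.306 with an estimated correlation. Adipocyte scores were 0.10 to 0.96 in the antibody libraries, 0.35 in AIA replicates 5 and 13, and -0.93, -0.88 and -0.13 in AIA replicates 18, 19 and 23. Nuclear-encoded genes of oxidative phosphorylation (0 of 26 called, 5 adjusted over the list alone), Schwann cell and nerve genes (0 of 12, and 4) and endothelial genes (0 of 18, and 0) had camera adjusted p = 1.25e-06, 0.00499 and 0.0226, and adjusted p = 0.443, 0.294 and 0.61 with an estimated correlation. Without antibody replicate 21_8 the endothelial list was at adjusted p = 0.148. Among genes with no overlap of the groups, large increases included Npr3, the clearance receptor of natriuretic peptides (5.02-fold, edgeR adjusted p = 0.0107), Grifin, encoding a galectin-related protein (4.14-fold), Nnat, encoding neuronatin (3.66-fold), Grb14, an adaptor that inhibits the insulin receptor (3.14-fold), and the dipeptidase gene Dpep1 (3.04-fold). Large decreases without overlap included Anxa8 (15.5-fold lower), Megf6 (15.2-fold), Ptprv (14.5-fold), Ccn4 (11.5-fold) and Cthrc1 (9.90-fold), a collagen triple helix repeat protein of activated fibroblasts. Their log2 CPM spread widely in AIA, with SDs of 2.17, 1.86, 2.09, 1.70 and 1.80. In the antibody group the SDs were 0.578, 0.121, 0.222, 0.269 and 0.248. These folds therefore do not hold alike for each AIA library, and Anxa8 was low in the antibody group (mean -0.97).

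**Figure D3:**
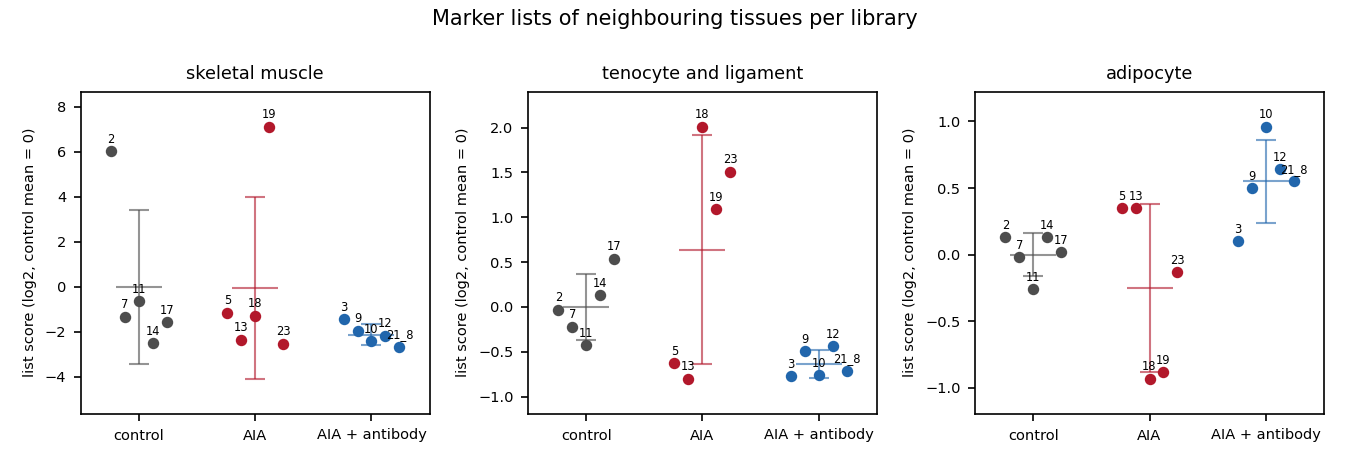
Scores of the skeletal muscle, tendon and ligament, and adipocyte marker lists per library (log2, control mean set to 0, vertical axis) in the 3 groups. Points are libraries with their replicate numbers and bars the mean ± SD of 5; muscle markers stand at 7.12 in AIA replicate 19 and 6.02 in control replicate 2, and the adipocyte score is lowest in AIA replicates 18 (-0.93) and 19 (-0.88).

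Between the antibody and AIA groups 294 genes were higher and 641 lower, 80 and 328 of them by at least 2-fold. Of the 935 genes, 412 had no overlap of the groups, and 3.81% of all tested genes had none, against 0.794% by chance. These counts rest on single libraries and on the model. They were 754 higher and 1278 lower without AIA replicate 5, 698 and 1217 without AIA replicate 13, 49 and 174 without AIA replicate 18, 53 and 222 without AIA replicate 19, and 71 and 173 without AIA replicate 23. Without antibody replicates 9, 10, 12 and 21_8 they were 110 and 358, 48 and 139, 131 and 592, and 107 and 198. A fit of only the 10 libraries called 35 and 77, removal of the 2 libraries with muscle transcripts left 46 and 174, and with the adipocyte score as a covariate edgeR called 0 and 0, with 960 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0871. With that covariate the camera calls of 10 lists were lost, among them cell cycle (adjusted p = 0.111), oxidative phosphorylation (0.6) and tendon and ligament (0.521), while matrix (5.4e-06) and macrophage (2.48e-09) lists stayed called lower, with 0 single genes called. The matrix median went from -1.19 to -0.525 with the covariate, and the median absolute log2 fold change of the 935 genes from 0.923 to 0.562. With 1 library left out, the calls of Vcan, Cd3e, Mrc1, Gpnmb, Cd80, C1s, C1qa, Mmp16, Tyrobp, Tnfrsf11b, Top2a, Comp, Gbp5, Tap1, Lep, Slc2a4, Nnat and Anxa8 were each lost at least once. C1qa and Tyrobp lost theirs in 8 of 10 runs. Of the 21 lists called by camera (5 higher, 16 lower), 0 passed with an estimated correlation and 15 lists passed with fry.

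Genes that AIA changed and the antibody group showed changed back were counted next. Of the 817 genes higher in AIA, 232 were lower in antibody against AIA (32.6 for independent lists), and of the 553 lower in AIA, 50 were higher (10.1 for independent lists). In the same direction there were 6 and 1. Of the 282 genes, 272 were not called in antibody against control. Choosing genes with calls in opposite directions favours this, so it does not by itself show a return to control level. The 8 with the lowest p were Adamts16, a metalloproteinase (5.98-fold lower in antibody against AIA, edgeR adjusted p = 0.000903), Slfn13 (1.79-fold lower), Mmp2 (3.32-fold lower), Ptprn (2.83-fold lower), Ripor2 (2.01-fold lower), the elastin cross-linking gene Loxl1 (2.17-fold lower), LOC120098543 (3.07-fold lower), and Fgf1, a fibroblast growth factor (2.29-fold higher). Among the lists, 10 of the 14 matrix genes called in AIA moved back, as did 6 of 9 matrix metalloproteinases and aggrecanases, 7 of 15 T and NK genes, 7 of 19 cell cycle genes and 5 of 8 MHC class II genes. Over all genes, 28.4% of those higher in AIA and 9.04% of those lower in AIA moved back. In other lists, 0 of 7 endothelial, 1 of 7 neutrophil, 0 of 6 lining fibroblast and 1 of 9 NF-kappaB target genes moved back. Of these, 7, 6, 6 and 6 genes stayed called against control. The 6 lining fibroblast genes were all lower in AIA, so 0 of 6 is near the share of 9.04%. The difference between lists was not tested.

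Both comparisons use the same AIA libraries, which alone gives opposite signs. In simulated groups with no effect, 81.5% ± 1.07 (SD) of the 1370 genes of largest difference had opposite signs. Among the genes called in AIA the observed share was 78.7%. These shares are not directly comparable, since the genes were chosen by size in 1 and by adjusted p in the other. Simulated genes were also independent, so that SD is likely too small. The AIA libraries were then split, so that no AIA library served in both comparisons. Of the genes called in AIA, 70.9% ± 6.61 (SD over 10 splits) then had the opposite sign. Among the simulated genes of largest difference the share was 50.1%. The simulation held no subgroup of libraries, whereas AIA replicates 18, 19 and 23 share high matrix and cell cycle scores. Most splits place some of these 3 libraries on both sides. The split values therefore cannot tell a change back under the antibody from a trait of those 3 libraries. A mean of 64 genes (range 1 to 144) were called in both in opposite directions, against 8.10 in the same direction. The covariance of both log2 fold changes across genes was -0.131 with shared libraries and -0.0404 in simulation, a difference of -0.0905, and -0.0778 ± 0.0213 with split libraries, which became -0.0233 for genes with an average log2 CPM of at least 3. The correlation across genes, which are not independent replicates, was -0.544 shared, -0.501 simulated and -0.279 split. The 282 became 804, 591, 82, 95 and 88 without AIA replicates 5, 13, 18, 19 and 23, 166, 84 and 127 without antibody replicates 9, 10 and 21_8, 178 without control replicate 14, and 0 with the adipocyte score as a covariate in edgeR, for which the unadjusted count in antibody against AIA is given above.

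**Figure D4:**
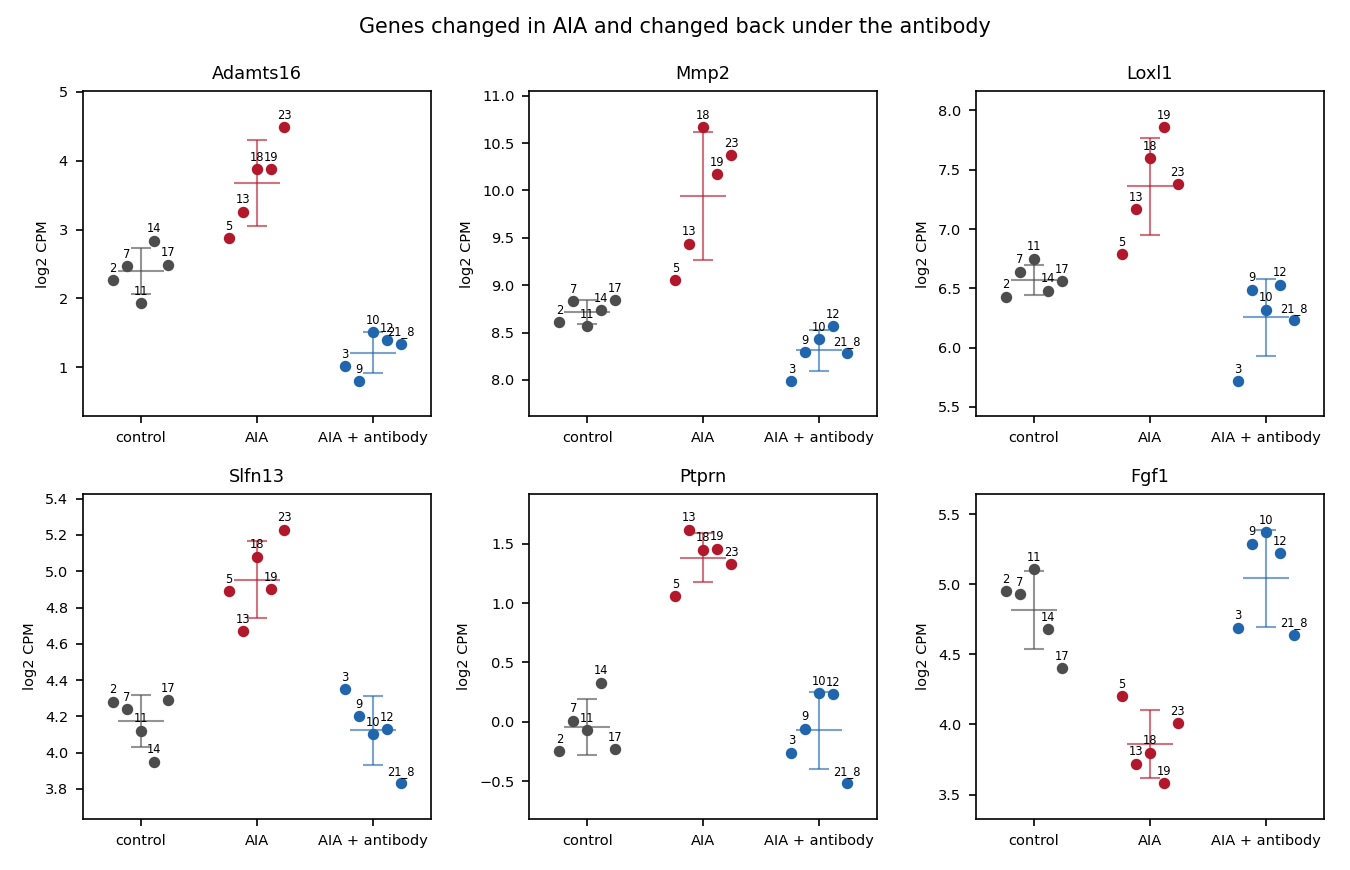
Levels of 6 of the 8 genes of lowest p among those changed in AIA and changed back in the antibody group (log2 CPM per library, vertical axis). Points are libraries with their replicate numbers and bars the mean ± SD of 5; for Adamts16 the means were 3.68 in AIA and 1.21 in the antibody group, and for Fgf1 3.86 and 5.04.

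Compared with control, the antibody group had high neutrophil, endothelial and interferon transcripts and low macrophage and lining fibroblast transcripts. Of 15 neutrophil genes, 10 were higher (14 adjusted over the list alone), including S100a9 (log2 fold change 3.55 ± 0.88) and Elane, encoding neutrophil elastase (3.71 ± 0.82). Tested together, the camera adjusted p was 1.31e-09, and the adjusted p = 0.388 with an estimated correlation. Erythroid and marrow genes moved with them, with scores of 0.53 to 1.60 in the antibody group and 0.52 to 1.92 in AIA. AIA replicate 13 was the highest AIA library for both lists (3.81 and 1.92). Blood or marrow in the piece was not tested as a source here either. Endothelial genes were higher in 8 of 18 (9 higher and 1 lower adjusted over the list alone), with Sele at 2.58 ± 0.29, Selp at 2.14 ± 0.24 and Ackr1, a chemokine-binding receptor of venules, at 1.91 ± 0.17; camera adjusted p was 6.75e-08 and the adjusted p = 0.388 with an estimated correlation. Of 26 interferon response genes, 9 were higher (12 adjusted over the list alone), including the peptide transporter Tap1 (0.67 ± 0.09), the immunoproteasome subunit Psmb8 (0.66 ± 0.12) and Cxcl10 (1.28 ± 0.37). By camera the adjusted p was 7.8e-08, and the adjusted p = 0.465 with an estimated correlation. Macrophage genes were lower in 8 of 19 (14 adjusted over the list alone), among them the haemoglobin scavenger receptor Cd163 (-1.10 ± 0.27) and Folr2 (-0.96 ± 0.22). For this list the camera adjusted p was 1.1e-08, and the adjusted p = 0.465 with an estimated correlation. Macrophage scores were -1.17 to -0.29 in the antibody libraries, -0.52 to 0.24 in AIA and -0.25 to 0.38 in control. Lining fibroblast genes were lower in 7 of 12 (8 adjusted over the list alone), including Prg4, encoding the joint lubricant lubricin (-0.94 ± 0.22), and Tmem196 (-1.27 ± 0.18). Camera gave adjusted p = 9.29e-05, and adjusted p = 0.388 with an estimated correlation.

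Other lists moved less or by fewer members. T and NK genes were higher in 3 and lower in 1 of 19 (5 and 1 adjusted over the list alone), with Nkg7 at 1.88 ± 0.52 and Cd4 at -0.79 ± 0.20, erythroid genes higher in 6 and lower in 1 of 18 (11 and 2 adjusted over the list alone), NF-kappaB targets higher in 7 and lower in 1 of 22 (9 and 1), and JAK-STAT3 and acute phase genes higher in 4 of 19 (7 and 3), with Lcn2 at 2.38 ± 0.25. Their camera adjusted p values were 0.012, 8.82e-05, 0.00541 and 0.013, and adjusted p = 0.465, 0.465, 0.465 and 0.652 with an estimated correlation. Chondrocyte genes were lower in 3 of 15 (3 adjusted over the list alone) and matrix genes in 4 of 30 with 1 higher (5 and 1), including decorin (Dcn, -1.02 ± 0.15), with camera adjusted p = 0.018 and 0.0412 and adjusted p = 0.692 and 0.745 with an estimated correlation. Oxidative phosphorylation, adipocyte and cell cycle genes had 0 of 26, 0 of 18 and 0 of 30 called, with camera adjusted p = 0.000166, 0.00155 and 0.0204 and adjusted p = 0.745, 0.712 and 0.745 with an estimated correlation. Osteoclast differentiation genes were higher in 4 and lower in 0 of 20 (5 and 8 adjusted over the list alone), namely Oscar (2.41 ± 0.54), Car2 (1.24 ± 0.37), Acp5 (0.91 ± 0.22) and Tnfrsf11a (0.69 ± 0.17), and the list was not called (camera adjusted p = 0.303). Without control replicate 17 the matrix, chondrocyte and JAK-STAT3 lists were no longer called (adjusted p = 0.106, 0.0773 and 0.0629), nor was cell cycle without antibody replicate 9 (0.0922).

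Against control, 543 genes were higher and 748 lower in the antibody group, 175 and 217 of them by at least 2-fold. Among genes with no overlap of the groups, large increases included Ubd (98.4-fold, edgeR adjusted p = 7.42e-07), Cmahp (15.9-fold), C3 (9.86-fold), Scnn1g, a subunit of the epithelial sodium channel (7.53-fold), the lipoxygenase gene Alox15 (6.32-fold) and Meox1, a transcription factor of mesenchymal cells (5.84-fold). Large decreases without overlap included Anxa8 (9.48-fold lower), Cd109 (5.51-fold lower), Grem1 (5.22-fold lower), Tnr (5.15-fold lower), the collagen-binding integrin Itga11 (4.33-fold lower) and Siglec10 (3.81-fold lower). Of the genes higher in AIA, 246 or 30.1% were called higher here too (27.6 for independent lists), and of the genes lower in AIA, 54.8% were called lower (25.8 genes for independent lists). The values for independent lists leave out that both comparisons share the control libraries, which favours calls in the same direction. With the control libraries split between the comparisons, 88 ± 29.3 (SD over splits) genes were called the same way in both and 0 opposite ways. Of the 1291 genes, 942 had no overlap of the groups, and 9.54% of all tested genes had none, against 0.794% by chance. The counts fell to 288 higher and 466 lower without control replicate 2, 301 and 407 without antibody replicate 10, and 348 and 433 without antibody replicate 21_8, and the higher count to 349 and 330 without control replicates 11 and 14. With the adipocyte score as a covariate they were 352 and 369, and of the 14 lists called by camera (10 higher, 4 lower) 0 passed with an estimated correlation. With 1 library left out, the calls of Itgb5, S100a9, Cxcl10, Cd163, Prg4, Nkg7, Cd4, Acp5, Car2, Tnfrsf11a, Alox15, Anxa8 and Itga11 were each lost at least once. Car2 lost its call in 8 of 10 runs.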

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

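The tests of the cause of the matrix pattern below were all chosen only after the pattern was seen. Within each group of 5 libraries, the highest and lowest values of each list score and named gene were compared with the rest, and a value was picked out where its gap to the nearest library exceeded 0.71 of the range of the group. Chance picks out about 1 in 20 groups, or 18.2 of the 363 groups tested, and 20 were found, so most of these need no cause. In control they were the B and plasma cell score of replicate 14 (-0.586), the skeletal muscle score of replicate 2 (6.02), and log2 CPM of Angptl2 in replicate 17 (7.68), Megf6 in replicate 14 (0.437), Grem1 in replicate 7 (1.46) and Folr2 in replicate 11 (7.59). In AIA they were the osteoclast differentiation (0.16) and complement (0.0515) scores and Il1rn (2) of replicate 5, the endothelial score of replicate 23 (0.22), and the skeletal muscle score (7.12) and Angptl2 (6.42) of replicate 19. In the antibody group they were the scores of osteoblast and bone formation (0.62) and osteoblast and osteocyte (0.87) and Gbp5 (5.24) of replicate 3, and the TGF-beta score (-0.345) and Anxa8 (-1.98) of replicate 10. The others there were Psmb8 (5.70) and Alox15 (4.15) of replicate 9 and Cd3e (-0.124) of replicate 21_8.

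Matrix and cell cycle scores were highest in AIA replicates 18, 19 and 23, although cell cycle scores of AIA replicates 5 (0.33) and 13 (0.50) and antibody replicates 3 (0.63), 9 (0.76), 10 (0.40) and 12 (0.41) also passed the control maximum of 0.16. Skeletal muscle in the dissected piece is not the likely cause, since 2 of the 3 libraries had muscle scores no higher than the muscle-poor controls. Tendon or ligament in the piece may contribute, since the median of tendon markers was at least 1.53 above control in each of the 3 (control SD 0.332), although fibrotic synovium could express the same genes. In each of the 3, the matrix score was at least 1.22 above the mean of endothelial, macrophage, pericyte and Schwann lists (control SD 0.436). This does not exclude a smaller share of adipose tissue as the whole cause. The 3 libraries were picked for high matrix scores, which favours such a gap, and the Schwann list was itself lower in AIA. The smallest gap of the matrix score to the highest of those lists (0.589, control SD 0.479) was too small to decide on a partial share. Adipocyte scores of replicates 18 (-0.933) and 19 (-0.878) lay below the control range of -0.26 to 0.132. That of replicate 23 (-0.126) lay inside it, so the score shows no smaller adipose share there, which is 1 library of the 3. More severe arthritis in these rats, the biological explanation the design allows, remains open and was not tested, since no joint score was used here.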

How the results depend on the processing

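No paired analysis was possible because the groups share no replicate numbers. No Angptl4 difference or named gene reversed direction in the settings it was run under. For named genes these were DESeq2 size factors, the DESeq2 Wald test and leaving out each library, and for Angptl4 also limma on log2(FPKM + 1). Of 121 named gene results, 121 kept their call with DESeq2 size factors and 121 with the DESeq2 Wald test, and 84 kept it whichever library was left out, while 37 lost it at least once. In AIA against control the 817 higher genes became 532 in a fit of only the 10 libraries compared, 366 and 368 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 498 with a log2 fold change of at least 1; the 553 lower genes became 857 with voom sample weights and 158 with that fold limit. In antibody against AIA the 294 higher and 641 lower genes became 648 and 1238 with DESeq2, 35 and 77 in a fit of 10 libraries, 1304 and 1424 with voom sample weights, 87 and 288 with the skeletal muscle score as a covariate, 0 and 0 with the adipocyte score, and 80 and 328 with the fold limit, and the lower genes 334 and 340 with FPKM. In antibody against control the 543 higher and 748 lower genes became 1005 and 1125 with voom sample weights, 352 and 369 with the adipocyte score, and 175 and 217 with the fold limit, and the higher genes 906 with DESeq2. Removal of both libraries with muscle transcripts, chosen after seeing the data, gave 334 and 238, 46 and 174, and 277 and 480 higher and lower genes in the 3 comparisons, with fewer libraries in the fit. The lists called fell from 15, 21 and 14 to 1, 0 and 0 with an estimated correlation. They fell from 21 to 13 with the adipocyte score, a setting added for lists after the data were seen. There the skeletal muscle (median log2 fold change from -6.60 to 0.07) and adipocyte (from 0.65 to -0.03) lists reversed sign and lost their calls. For the adipocyte list this follows by construction, since the covariate is its own score. The 282 genes moved back became 615 with DESeq2 and 144 with the muscle score, and, in settings chosen after seeing the data, 0 with the adipocyte score and 66 without the muscle libraries. The covariance of -0.0778 with split libraries became -0.0233 for genes with an average log2 CPM of at least 3. That limit drops the noisier genes. Simulated unchanged groups gave a split covariance of 1.63e-05 ± 0.00246 (SD), so the loss of noise does not by itself explain the fall. The Angptl4 difference between antibody and control (1.01) passed with the DESeq2 Wald test, added after the data were seen (1.01, adjusted p = 0.0117). Except where the construction is named, the cause was not tested. Leaving out 1 library gave 522 to 1147 higher and 369 to 796 lower genes in AIA against control, 48 to 754 and 139 to 1278 in antibody against AIA, and 288 to 510 and 407 to 802 in antibody against control. It gave 15 to 18, 18 to 25 and 12 to 17 lists, 82 to 804 genes moved back, 68.5% to 72.3% opposite signs, a covariance of -0.0831 to -0.0707, and Angptl4 differences of 0.318 to 0.818, 0.188 to 0.684 and 0.874 to 1.11. For the adipocyte covariate, the median absolute log2 fold change of the 935 called genes went from 0.923 to 0.562 and the median SE from 0.208 to 0.254, and 100% kept their direction. With 5 libraries per group, smaller changes are often missed, since 26.9% to 40.9% of simulated 1.5-fold changes were called.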

Other observations

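All tests in this part were chosen only after the results were seen, except the splits of the libraries and the 2 correlations with the adipocyte score among called genes. Xist, expressed from the inactive X chromosome, was present in every library (mean log2 CPM 9.30 ± 0.58 in control, 9.18 ± 0.51 in AIA and 9.24 ± 0.45 in the antibody group, SD, n = 5). Within groups, 536 genes correlated with it at r over 0.8 and 533 at r under -0.8. The nuclear speckle genes Srrm2 (r = 0.953), Son (0.949) and Pnisr (0.961) rose with Xist, and 102 ribosomal protein genes had a median r of -0.848.

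The genes that differ between antibody-treated and arthritic rats may in part reflect a larger adipose share in the antibody libraries. Of the genes higher under the antibody, 79.1% correlated positively with the adipocyte score within the control and antibody groups, against 47.5% of other genes. Of the lower genes, 50.7% correlated negatively, against 52.5% of other genes, so that test shows no link, but with the score as a covariate 0 genes stayed called and the matrix median went from -1.19 to -0.525, so a part played by adipose share stays open. The endothelial minus macrophage score differed by 0.882 ± 0.245 (SE, exact permutation p = 0.0159). Dilution alone would lower both lists together only if adipose tissue held few cells of either type, which was not measured. That difference, picked after the list results were seen, therefore does not decide on adipose share. An effect of the antibody on synovial cells remains open, since the labels name no group given a control antibody.

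For the Xist pattern, transcript length may be involved, since the correlation with Xist rose with gene length (Spearman rho = 0.475, median lengths 6928 and 1160 bases for the positive and negative genes). Library size was not decided (r = -0.424, permutation p = 0.157), and neither was bone or marrow in the piece (r = 0.703 with the osteoblast and osteocyte score, adjusted p = 0.0324 over 3 relations, and 0.576 without the 2 farthest libraries). RNA quality and nuclear RNA content were not measured in the data used here, and no biological explanation was tested. Adipocyte content as a source of the Angptl4 spread found no backing, with a within-group r of -0.0496 (permutation p = 0.905).

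Regrouping the 10 libraries of a comparison in 100 ways, the real grouping included, tested whether chance could give as many called genes. For AIA against control 1 of the 100, the real one, reached 1370 genes, and the highest other reached 519. For antibody against control 1 reached 1291, and the highest other reached 6. For antibody against AIA 2 reached 935, since a split that exchanges AIA replicate 13 with antibody replicate 3 gave 1033, and a split that exchanges AIA replicate 5 with antibody replicate 12 gave 783, so AIA replicates 5 and 13 resemble the antibody libraries in part. By the limit set beforehand (fewer than 5 of 100), so many calls were rare among random groupings in all 3. In antibody against AIA, however, a wrong grouping gave more calls than the real one. The number of calls there does not by itself tell the real groups from a mixed set of libraries.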
